A study of Mus musculus with 2 samples.

How the data were processed

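RNA from primary mouse megakaryocytes of 2 genotypes was compared, wild type and null for the p45 subunit of NF-E2. Per the labels, cells of fetal liver at embryonic day 14.5 from crosses of heterozygous mice of mixed background were cultured for 4 days in 20% serum with thrombopoietin at 50 ng/ml, and cells bearing CD41 were then taken by magnetic selection. The labels name female and male fetuses for both genotypes and do not say how many livers went into each culture. From 1 µg of total RNA, biotin-labelled target was made by reverse transcription from an oligo-dT primer and in vitro transcription, per the labels' protocols, so the signals weigh the 3′ part of each transcript. Each genotype has 1 array (n = 1), and the genotype of each array was taken from its label.

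The deposited values are intensities on a linear scale, 1 per probe set, and were made with MAS5, per the submitters' processing notes. The version, target intensity and detection calls of that step are not given in the sources used here. Each array held 45101 probe sets, of which 64 were controls, and the 2% trimmed mean was 100.0 on both arrays, so the arrays had already been scaled to a common mean and were used as deposited. Median intensities were 13.6 on the wild-type and 12.9 on the p45-null array, the highest were 10708.9 and 9585.7, and 2 and 3 values were 0. The values are relative to each array's own mean, so a difference in the amount of RNA per cell cannot be seen in them.

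Probe sets were named from the platform annotation. It listed 35890 probe sets, of which 34958 had 1 gene symbol and 932 had several, while 9211 were unnamed here. Symbols were checked through gene identifiers against a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them, and the same table gave synonyms and gene order. No build is named for the arrays, so no coordinates are given. A gene was represented by its probe set with the highest mean log2 intensity over the arrays, which gave 18193 genes. The fold given for a gene is that of this 1 probe set, and its other bright probe sets can fall short of 2-fold.

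Intensities below the 40th percentile of all values, 8.3, were raised to that floor before log2 was taken. A gene was measured if at least 1 array lay above the floor (14133 genes) and passed the brightness rule if its brighter array reached the 60th percentile, 25.2 (10335 genes). The log2 ratio is p45-null over wild type. Where the dimmer array lay at the floor the ratio is a bound and is written as at least so many fold. With 1 array per genotype there is no test, no p-value and no standard deviation, and a gene is called higher or lower when its ratio reaches 2-fold and it passes the brightness rule. The number of arrays limits the precision. The only repeat measurement is the difference in log2 ratio between the 2 brightest probe sets of a gene, which covers probe and hybridisation error and leaves out differences between cultures and animals.

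For each of 34 gene lists (platelet parts and signalling, transcription factors, markers of other cell types, stress, growth and control genes) the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins (seed 15). This percentile describes these 2 arrays and is no test of genotype. The lists, the brightness rule, the floor and the rule for naming genes were set before the data were examined. That rule takes Nfe2, the 12 highest and 12 lowest ratios among officially named genes whose probe sets agree in sign, all reported p45 targets, and in each other list up to 4 members with the largest ratios together with members at least 2-fold different. Members named outside it were chosen after their values were seen: Itga2b, Itgb3, Pf4, Ppbp, Gata1, Nqo1, Gclm, Gclc, Txnrd1, Cpa3, Kit, Hspa5, Afp, Cd79a, Pax5, Rag1 and all genes of the lists added later. Genes on chromosome 15 beside Nfe2 were compared with random genes in the same way, and Prr13 and Map3k12 among them were also named after their values were seen.

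The calling steps were tested on a simulated p45-null array (10097 genes). It was made from the wild-type array with noise of the size seen between probe sets of 1 gene. This noise leaves out differences between cultures and animals, so the rates that follow do not cover them. Of 50 genes each, 6% were called at a true ratio of 1.5-fold, 88% at 2.5-fold, and 100% at 4-fold and 8-fold. These changed genes were drawn only from genes that reached the brightness rule on the wild-type array. The recovery rates therefore do not cover genes that are dimmer there. Of 9897 unchanged genes, 192 or 1.94% were called. In a separate step on 13248 genes, 7% of unchanged random lists of 20 genes lay in the outer tails that should hold 5%.

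Alternatives were other scalings (equal medians, quantile normalization, loess with span 0.4), other floors, a pseudocount, other brightness rules, other ways to combine probe sets and unmatched random lists. A floor at the 75th percentile and a count that needs both of the 2 brightest probe sets of a gene were added after the data were seen, as were 7 further gene lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.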

Results

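Megakaryocytes, the large polyploid cells that shed platelets, were compared between wild-type fetuses and fetuses without the p45 subunit of NF-E2. This subunit is encoded by Nfe2 and binds DNA as a partner of the small Maf proteins. The comparison asks which transcripts differ in megakaryocytes when p45 is missing. The cells were grown from fetal liver with thrombopoietin, the growth factor of this lineage, and selected for CD41, the platelet integrin chain encoded by Itga2b. There was 1 array per genotype and no replicate, so every difference is a ratio of 2 arrays, with no test behind it.

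Signals of the arrays were compared first. Across 16687 probe sets bright on both, which are not independent replicates, log2 intensities correlated with Pearson r = 0.93. The 3′ to 5′ ratio was 0.772 and 0.725 for Gapdh, 1.15 and 1.23 for beta-actin, and 3.12 and 3.03 for the transferrin receptor (wild type, then p45-null). In 12 probe sets for the hybridisation spike-ins bioC, bioD and cre the log2 ratio lay between -0.21 and 0.00. All probe sets for the spike-in bioB lay below the floor of 8.3 on both arrays. Control probe sets for 18S ribosomal RNA differed strongly, being 86.3-fold lower at the 5′ end, 6.65-fold in the middle and 4.86-fold at the 3′ end in the p45-null array. Between the 2 brightest probe sets of a gene, log2 ratios differed by a median of 0.28 over 4568 genes, and by 0.87 at the 90th percentile.

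Nfe2 itself, measured by 1 probe set, had an intensity of 2208 in wild-type and 729 in p45-null cells, 3.03-fold lower. Its signal in the p45-null array was well above the floor. Where this probe set lies relative to the removed part of the gene is not given in the sources used here, so it cannot check the label by itself.

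Platelet transcripts were among the most strongly reduced in p45-null cells. Tubb1, the beta-tubulin of the platelet marginal band, was 103-fold lower, at 3233 in wild-type and 31.3 in p45-null cells. The serotonin transporter Slc6a4 was 42.3-fold lower, Clec1b, the platelet receptor for podoplanin, 32.7-fold, the collagen receptor Gp6 31.9-fold, and thromboxane synthase Tbxas1 had a log2 ratio of -3.91. In the other direction, the embryonic globin Hbb-bh1 was 31.4-fold higher, the erythroid heme enzyme Alas2 at least 29.2-fold, and the scavenger receptor Cd36 7.73-fold. Macrophage, hepatocyte and stromal markers were also higher in the p45-null array.

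Of 10335 genes passing the brightness rule, 1075 (10.4%) were at least 2-fold higher and 537 (5.20%) at least 2-fold lower in p45-null cells. Higher genes made up 66.7% of those called. At least 4-fold, 193 genes were higher and 103 lower, and at least 8-fold, 7 were higher and 22 lower. The median log2 ratio was 0.11, and with equal medians it was -0.02, with 878 genes higher and 678 lower, so that 56.4% of calls were higher. Of 542 called genes with a second bright probe set, 519 had the same direction in it and 363 were also at least 2-fold different. In 112 called genes, 1 array lay at the floor.

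**Figure D1:**
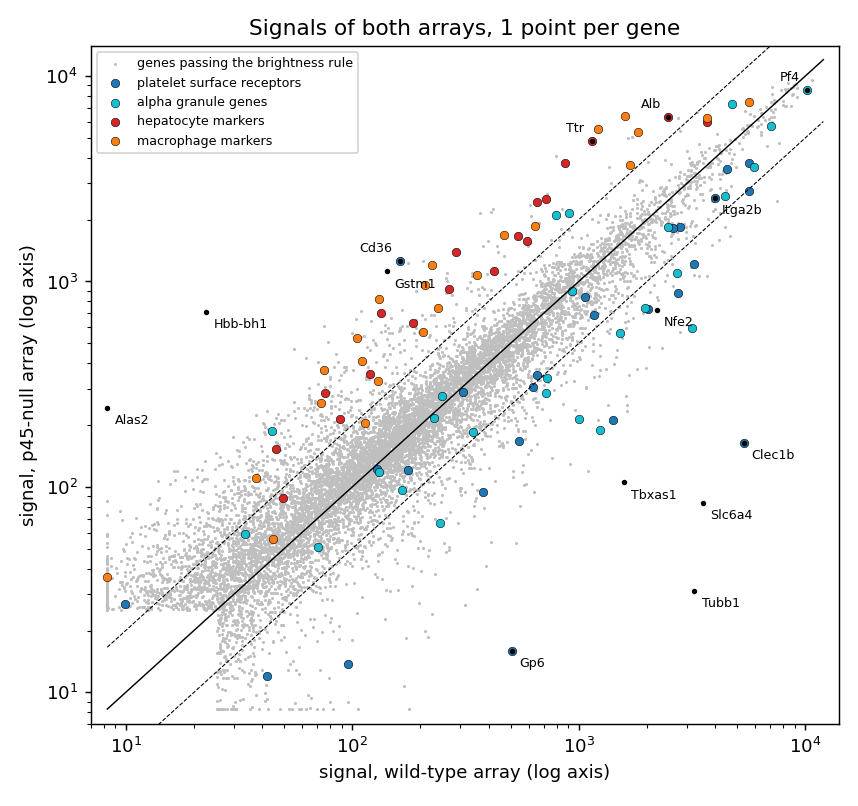
Intensity of each gene on the wild-type array (horizontal, log axis) and on the p45-null array (vertical, log axis), 1 point per gene passing the brightness rule, with values below the floor of 8.3 drawn at it, the solid line at equal intensity and dashed lines at 2-fold. Platelet receptor and alpha granule genes lie mostly below the solid line (Gp6 at 508 and 15.9, Clec1b at 5354 and 164), while hepatocyte and macrophage markers lie above it (Ttr at 1139 and 4819).

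Other genes with the largest decreases were Fcer1a, a chain of the high-affinity IgE receptor (at least 21.5-fold), the protease gene Gzmb (15.7-fold), the prokineticin receptor Prokr1 (at least 12.7-fold), the glutathione transferase Gsta2 (11.8-fold), the hemojuvelin gene Hjv (11.6-fold), Ttll11 of the tubulin tyrosine ligase-like family (11.2-fold) and the scaffold gene Homer2 (10.6-fold). Among the 12 largest increases, Agmo was at least 10.2-fold higher, Cyp2d10 at least 8.82-fold, the cornified envelope gene Sprr1a 8.43-fold, the cytidine deaminase Cda 8.13-fold, the glutathione transferases Gsta4 8.12-fold and Gstm1 7.88-fold, the tetraspanin Tspan33 7.73-fold, the trefoil factor Tff3 7.32-fold and Abr 7.22-fold. More than 1 bright probe set was present for 4 of the 12 higher and 3 of the 12 lower genes. The 3 bright probe sets of Tspan33 disagreed in size, with log2 ratios from 0.43 to 2.95, so not all of them reached 2-fold.

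**Figure D2:**
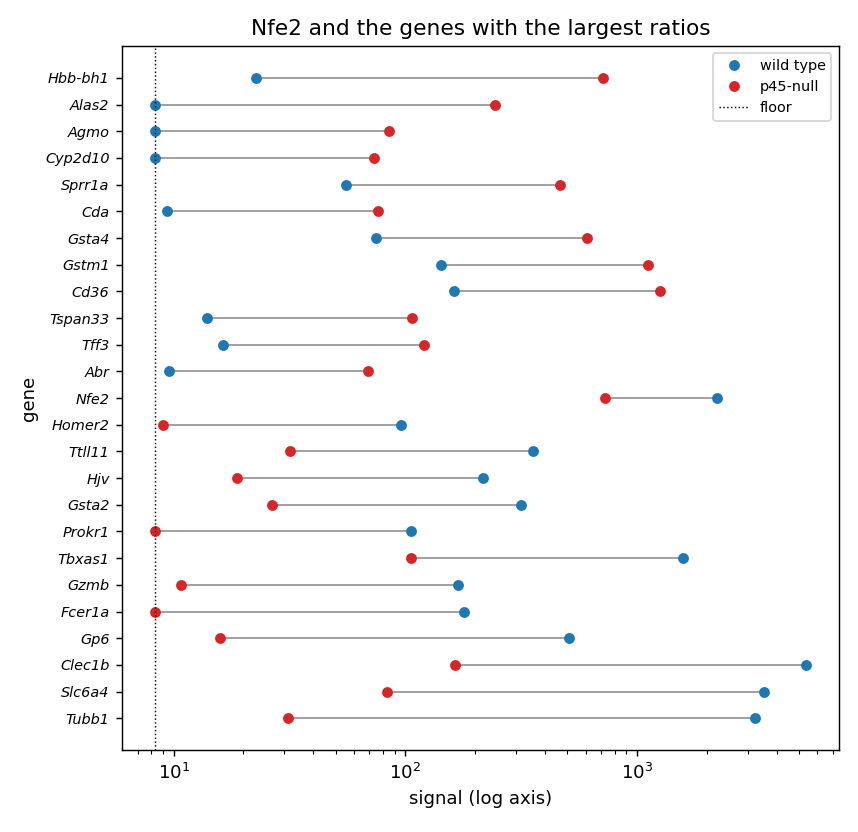
Intensity (horizontal, log axis) in wild-type (blue) and p45-null (red) cells for Nfe2 and the 12 genes with the largest ratio in each direction (vertical), with the floor of 8.3 as a dotted line and lower values drawn at it. Nfe2 spans 2208 to 729, while Tubb1 spans 3233 to 31.3 and Hbb-bh1 runs the other way from 22.7 to 713.

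Genes that earlier studies had reported as p45 targets were lower as a group. Of 5 measured, 4 were at least 2-fold lower: Tubb1, Tbxas1, Casp12 (4.75-fold) and Rab27b (3.44-fold), a small GTPase of granule transport. Lims1, an adaptor of integrin adhesions, had a log2 ratio of -0.48, and its 5 bright probe sets ran from -1.01 to -0.48. The list median was -2.25, below all 10000 random lists, whose central 95% ran from -0.51 to 0.49. The 4 bright probe sets of Rab27b disagreed, from -1.83 to 0.94, and Hsd3b6, also reported as a target, had no probe set of its own here. All 5 genes also belong to other lists below.

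Of 25 surface receptors and adhesion molecules of platelets, 12 were at least 2-fold lower, 2 higher and 11 neither (median -0.90, percentile 0). Beside Clec1b and Gp6, the ADP receptor P2ry12 was 6.94-fold lower, the adhesion receptor Slamf1 6.72-fold, the prostacyclin receptor Ptgir 4.00-fold, and Gp5 and Gp9 of the von Willebrand factor receptor 3.12-fold and 2.66-fold. Both chains of the fibrinogen receptor had smaller ratios, with log2 values of -0.64 for Itga2b and -0.59 for Itgb3, while the collagen-binding chain Itga2 was 3.52-fold lower. Cd36 and the junctional adhesion molecule Jam3 (2.71-fold) were the 2 higher members. On the same arrays the hepatocyte and macrophage markers lay in the opposite direction, with medians of 1.75 and 1.64.

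Alpha granule genes had a median of -0.59 (percentile 0), with 9 of 26 at least 2-fold lower, 3 higher and 14 neither. Coagulation factor F5 was 6.56-fold lower, F13a1 5.30-fold, P-selectin (Selp) 4.67-fold, the granule sorting gene Vps33b 3.66-fold and Vwf 2.46-fold. The abundant chemokine genes Pf4 and Ppbp had log2 ratios of -0.25 and -0.30, at intensities of 10149 and 7031 in wild-type cells. Pf4 lay close to the highest intensity of that array, 10708.9, where ratios can be compressed. Gas6 (4.26-fold), Sparc (2.66-fold) and fibronectin Fn1 (2.39-fold) were higher, and these matrix and secreted proteins are also made by stromal cells, whose markers had a median of 1.02 on the same arrays.

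Dense granule genes had a median of -0.18 (percentile 1.74), with 3 of 18 at least 2-fold lower and 15 neither. The vesicular monoamine transporter Slc18a2 was 2.65-fold lower and Rab27a 2.07-fold. This list came inside the central 95% of random lists under several settings, for example at -0.11 and percentile 6.55 without probe sets prone to cross-hybridise.

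Among 27 tubulin and cytoskeletal genes of platelets, 3 were at least 2-fold lower and 24 neither, with 23 ratios below 0 and 4 above. The lower genes were Tubb1, the non-muscle myosin Myh9 (3.19-fold) and the myosin light chain kinase Mylk (2.11-fold). Not all bright probe sets reached 2-fold, as they ran from -2.49 to -0.68 for Myh9 and from -2.07 to -0.48 for Mylk. The median was -0.69 (percentile 0).

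Platelet signalling genes had a median of -0.53 (percentile 0). Of 31 bright members, 11 were at least 2-fold lower, among them the kinase Btk (3.33-fold), Rasgrp2, the activator of Rap1 in platelets (2.83-fold), and the calcium sensor Stim1 (2.79-fold). Parva, a partner of integrin-linked kinase, was 3.19-fold higher, and 19 were neither.

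Transcription factors of the lineage had a median of -0.46 (percentile 0.04), and 15 of 17 bright members were neither higher nor lower. Apart from Nfe2, Mllt3 was the only bright member at least 2-fold different, at 2.24-fold lower, and its log2 ratio was 0.31 without shared probe sets. Gata1 had a log2 ratio of -0.77. The list of CNC, Bach and small Maf factors, which share DNA sites and partners with p45, also held Nfe2 itself and Keap1, which is no such factor. Its median of -0.22 lay inside the random range (percentile 6.38). It lay below that range with bright members alone (-0.33, percentile 2.30) or the floor at the 75th percentile (-0.43, percentile 2.07). Nfe2 counts in each of these medians, and none was computed without it. The repressor gene Bach1 was 2.52-fold lower, Mafg had a log2 ratio of -0.79 and Nfe2l2, which encodes NRF2, -0.43.

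Genes of steroid and cholesterol synthesis had a median of -0.72 (percentile 0), with 4 of 16 bright members lower and 12 neither. Hsd17b1 was 4.03-fold lower (52 in wild-type and 12.9 in p45-null cells) and Hsd3b1 at least 3.69-fold (30.6 and below the floor). Both were dim. The farnesyl diphosphate synthase Fdps was 2.29-fold lower and Mvd of the mevalonate pathway 2.02-fold. In eicosanoid synthesis (median -0.33, percentile 0.83) Tbxas1 and Alox5ap, the activating protein of 5-lipoxygenase (2.98-fold), were lower, while the leukotriene C4 synthase Ltc4s (5.51-fold) and the prostaglandin D synthase Hpgds (2.30-fold) were higher and 6 of 10 bright members were neither.

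Genes regulated by NRF2, a transcription factor of the antioxidant response, had a higher median of 0.36 (percentile 99.99). Of 34 bright members 10 were at least 2-fold higher, 2 lower and 22 neither. Gsta4 and Gstm1 led, followed by the epoxide hydrolase Ephx1 (4.08-fold), heme oxygenase Hmox1 (3.68-fold) and Osgin1 (3.52-fold). Gsta2 and the sulfiredoxin gene Srxn1 (2.40-fold) were lower. Classical NRF2 targets went both ways, with log2 ratios of 0.91 for Nqo1, 0.44 for Txnrd1, -0.31 for Gclc and -0.93 for Gclm. On the same arrays the hepatocyte markers had a median of 1.75 and the macrophage markers 1.64. Other antioxidant enzymes (median -0.02, percentile 35.1) included the secreted peroxidase Gpx3, 3.67-fold higher, and the thioredoxin inhibitor Txnip, 2.81-fold lower. The NADPH oxidase list had a median of -0.31 (percentile 5.42), and its phagocyte catalytic chain Cybb was 2.46-fold higher.

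Embryonic globins were higher. Hbb-bh1, Hbb-y (5.12-fold) and Hba-x (4.05-fold) are globin genes of the embryonic lineage, and 3 of 4 bright globin members were higher and Hba-a2 3.13-fold lower (median 2.02, percentile 100). Hba-a2 was dim, at 35.7 in wild-type and 11.4 in p45-null cells, and so was Hba-x, at 11 and 44.6. Each lay close to the floor of 8.3 on 1 array. Adult globin probe sets shared by several genes were not used. Without shared probe sets, which removes Hbb-bh1 and Hbb-y, the globin median was -1.59 over the few dim members left. Other erythroid genes had a median of 0.48 (percentile 99.9), with 6 of 21 bright members higher, including the Rh-associated glycoprotein Rhag (at least 5.36-fold), the transcription factor Klf1 (3.19-fold) and carbonic anhydrase Car1 (2.58-fold), and 15 neither.

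Mast cell and basophil transcripts were lower, with 8 of 11 bright members at least 2-fold lower and 3 neither (median -1.42, percentile 0; -1.30 without Slc6a4). Beside Fcer1a and Gzmb, the IgE receptor chain Ms4a2 was 3.32-fold lower and the basophil protease Mcpt8 2.93-fold. Cpa3 had a log2 ratio of -0.76 and the receptor gene Kit 0.12.

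Macrophage markers were higher in 19 of 23 members and neither in 4 (median 1.64, percentile 100). The complement gene C1qc was 6.28-fold higher, the lysosomal glycoprotein Cd68 5.37-fold, Adgre1, which encodes F4/80, 3.72-fold and the receptor Csf1r 2.90-fold. Hepatocyte and hepatoblast markers were higher in 16 of 18 members and neither in 2 (median 1.75, percentile 100). Vitronectin (Vtn) was 5.22-fold higher, the retinol carrier Rbp4 4.85-fold, transthyretin (Ttr) 4.23-fold and albumin (Alb) 2.55-fold, from 2476 in wild-type to 6313 in p45-null cells. Stromal markers had a median of 1.02 (percentile 100), with 9 of 17 bright members higher, including Pdgfrb (3.66-fold) the matrix genes Mgp (3.22-fold) and Col3a1 (2.29-fold) and the actin-binding gene Tagln (2.66-fold), and 8 neither.

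Neutrophil genes had a median of 0.17 (percentile 85.6), with Lcn2 2.15-fold higher and 14 of 15 neither. Endothelial genes had a median of 0.06 (percentile 32.8), with the sinusoidal genes Clec4g (4.71-fold) and Lyve1 (at least 3.11-fold) lower and Flt4 (2.45-fold) higher. Dendritic and antigen presentation genes had a median of 0.36 (percentile 83.3, and 98.4 with the floor at the 50th percentile), with Irf8 2.52-fold higher. Stem and progenitor genes had a median of 0.23 (percentile 89.7), with Sox4 (2.86-fold), Cebpa (2.73-fold) and Spi1 (2.32-fold) higher. Slamf1 (6.72-fold) and the growth factor gene Angpt1 (2.49-fold) were lower, and 9 of 14 bright members were neither. In contrast, lymphoid markers had a median of 1.06 over 8 members (percentile 99.96), from the B cell linker Blnk (7.07-fold), the receptor Il7r (4.68-fold) and Cd3d (at least 3.46-fold), with only 4 bright members. Cd79b had a log2 ratio of -0.13, and 7 of the 15 lymphoid genes with a probe set, among them Cd79a, Pax5 and Rag1, lay at or below the floor on both arrays and did not enter the median.

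**Figure D3:**
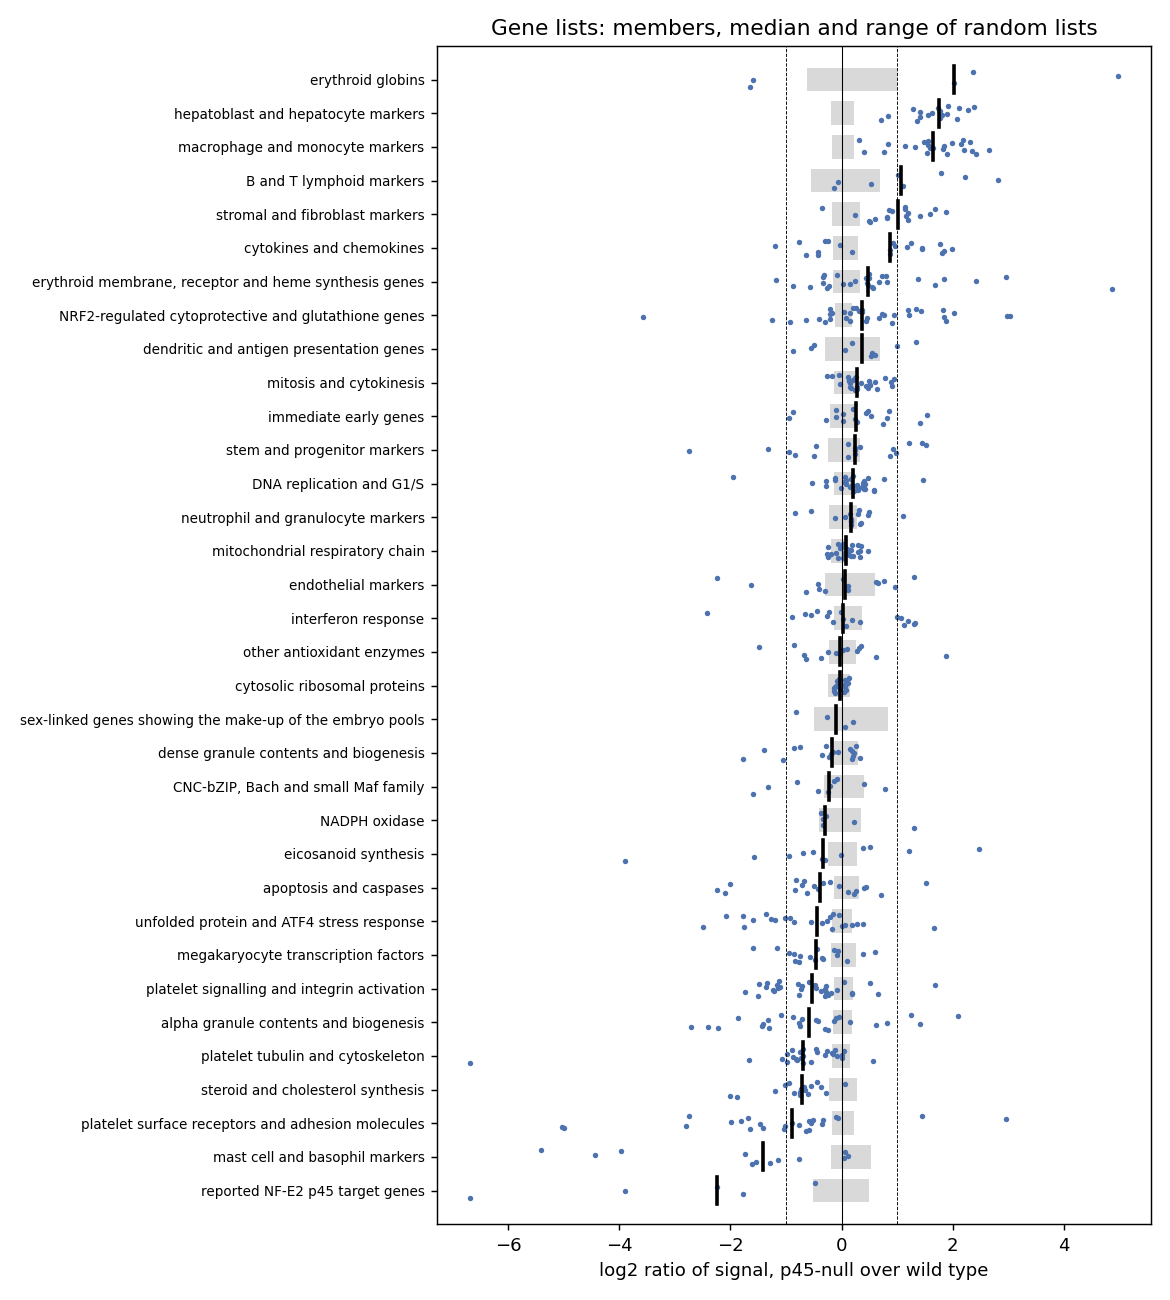
Log2 ratio of p45-null over wild type (horizontal) for the members of each of 34 gene lists (vertical), with a blue point per measured gene, a black bar at the list median, grey boxes for the central 95% of medians of 10000 random lists matched on level, and dashed lines at 2-fold. Platelet lists lie to the left (receptors at -0.90), hepatocyte and macrophage markers to the right (1.75 and 1.64), and ribosomal and respiratory chain genes near 0 (-0.03 and 0.08).

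The unfolded protein and ATF4 list had a median of -0.45 (percentile 0.01), with 9 of 24 at least 2-fold lower, 1 higher and 14 neither. The ATF4 target Trib3 was 5.66-fold lower, the endoplasmic reticulum genes Sdf2l1 4.25-fold and Creld2 3.41-fold, and Ddit3, which encodes CHOP, 3.39-fold, while Atf3 was 3.17-fold higher. The chaperone gene Hspa5 had a log2 ratio of -0.56. In the apoptosis list (median -0.38, percentile 0.02) Casp12, Casp4 (4.26-fold) and Bbc3, which encodes PUMA (4.01-fold), were lower and Pmaip1, which encodes NOXA, was 2.85-fold higher, with 16 of 20 neither.

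Of 28 genes of mitosis and cytokinesis, 24 had a ratio above 0 and 0 reached 2-fold (median 0.27, percentile 99.2, and 95.4 among random lists not matched on level). Ect2, which drives cleavage furrow formation, had a log2 ratio of 0.93 and the mitotic kinase Plk1 0.91. DNA replication and G1/S genes had a median of 0.21, just inside the random range (percentile 97.4) and above it in 5 settings, by at most percentile 99.2, with Ccnd1 (cyclin D1) 2.77-fold higher and Cdkn1b, the cell cycle inhibitor p27, 3.89-fold lower. The 3 bright probe sets of Ccnd1 ran from 0.32 to 1.47.

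Cytokine and chemokine genes had a median of 0.88 (percentile 100), with 8 of 18 bright members higher, 1 lower and 9 neither. The macrophage-attracting chemokines Ccl6 (3.97-fold) and Ccl2 (3.57-fold), Tnf (3.50-fold) and Cxcl1 (3.40-fold) were higher, and Ccl17 2.31-fold lower, on arrays whose macrophage markers had a median of 1.64. The 3 bright probe sets of Cxcl1 ran from 0.61 to 1.76. Immediate early genes had a median of 0.25 (percentile 98.1), with Dusp1 (2.89-fold) and Fosb (2.65-fold) higher and 16 of 18 neither. This list came inside the random range in 3 settings, at percentile 93.3 without shared probe sets, 88.9 among unmatched random lists and 95.8 with the floor at the 75th percentile. Interferon response genes went both ways (median 0.02, percentile 22.9), with 5 of 18 bright members higher, such as Ifit3 (2.47-fold) and Mx1 (2.27-fold), and the interferon-gamma-induced GTPase gene Igtp 5.34-fold lower.

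The respiratory chain had a median of 0.08 (percentile 91.5) and cytosolic ribosomal proteins -0.03 (percentile 55.0), with 0 of 28 and 0 of 17 genes at least 2-fold different. Sex-linked genes, which show the mix of fetuses in each culture, had a median of -0.10 (percentile 20.6). The list joins Xist, expressed in females, with Y-linked genes, and a change in the mix moves these in opposite directions. Its median therefore cannot show whether the mixes matched. Both arrays carried Xist (477 and 498) and the Y-linked Eif2s3y (187 and 215), in wild-type and p45-null cells. The 3 bright probe sets of Xist ran from -1.83 to 0.06, the Y-linked Uty had a log2 ratio of -0.81, and without shared probe sets the list median was -0.54 (percentile 1.67).

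Genes beside Nfe2 on chromosome 15 can carry sequence of the strain in which the gene was targeted. It lies near the chromosome's end, so 57 measured neighbours were compared, 50 on the one side and 7 on the other. Of these, 9 (15.8%) were at least 2-fold different, against 14.2% of all measured genes, which is at percentile 65.0 of random gene sets of that size. They included Prr13 (2.64-fold lower), Map3k12 (3.31-fold lower) and the keratin genes Krt7, Krt8 and Krt18, which were higher. None of the 40 genes of the platelet and reported-target lists that were at least 2-fold lower was among them.

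In all, 10 of the 34 lists had a median above the central 95% of random lists, 12 below and 12 inside. Members of a list are regulated together while those of a random list are not, so the percentiles overstate how unusual a list is. Each ratio also carries any difference between the cultures that is unrelated to p45.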

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

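No test was run on the values given here, which are control probe sets outside the comparison of genes that were singled out after the data were seen, because they passed the brightness rule and differed at least 2-fold between the arrays. The 3 probe sets for 18S ribosomal RNA were brighter in the wild-type array. The probe set at the 5′ end had an intensity of 4092.4 in wild-type and 47.4 in p45-null cells, the middle probe set 569.5 and 85.6, and the 3′ probe set 398.7 and 82.1. The 3′ probe set for pyruvate carboxylase had 18.6 in wild-type and 38.4 in p45-null cells, so that only the p45-null value reached the brightness rule of 25.2.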

How the results depend on the processing

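The floor at the 75th percentile and the need for both of the 2 brightest probe sets were chosen after the data were seen; all other settings were planned. Over 12 settings, 404 of 408 list medians moved by less than 1.5-fold, 3 by more and 1 reversed. Of 2185 ratios of 226 named genes under the settings, 2101 stayed, 83 moved, 61 of them toward 0, and 1 reversed. The count of higher genes (1075) moved to 545 with the brightness rule at the 75th percentile, 1818 for probe sets in place of genes, 314 with the floor at the 75th percentile and 232 with both of the 2 brightest probe sets. The count of lower genes (537) moved to 1414, 299 and 131 under the last 3 of these. Fewer genes can pass under a higher rule, a higher floor shrinks ratios of dim genes, and only 4568 genes have 2 bright probe sets. The globin median of 2.02 became -1.59 without shared probe sets, which removes Hbb-bh1 and Hbb-y, and 2.69 with the higher floor. The lymphoid median of 1.06 became 2.01 with bright members alone, of which there are 4. The median of the reported p45 targets became -2.84 with the higher floor. The ratio of Mllt3 became 0.31 without shared probe sets, and the cause was not tested. With other scalings the hepatocyte median was 1.63 to 1.72 and the platelet receptor median -1.02 to -0.88. Membership of the outer tails changed in at least 1 setting for 8 lists (dense granule, DNA replication, immediate early, mitosis, dendritic, CNC and Maf, globin and sex-linked), and lists with too few bright members had no percentile with the higher floor. No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out. Signal over background limits ratios of dim genes, since 38.8% and 41.2% of probe sets lay at the floor in wild-type and p45-null cells.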

Other observations

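The tests of the megakaryocyte share, of scaling, of dilution and of the hepatic part of the NRF2 list were chosen only after those results were seen, and so were the lists of epithelial genes, tubulin isotypes, tubulin ligases and the parts of the NRF2 list; the second hepatocyte and macrophage lists were written before their values were seen.

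Epithelial and bile duct genes were among the most raised transcripts of the p45-null array. Of 18 bright members 15 were at least 2-fold higher and 3 neither, with a median of 1.73 over 22 measured genes (percentile 100). The simple epithelial keratins Krt8, Krt18 and Krt19 had log2 ratios of 2.55, 2.40 and 2.32, the tight junction gene Cldn4 2.34 and E-cadherin (Cdh1) 1.98, whereas the epithelial adhesion gene Epcam had 0.07. Krt8 reached an intensity of 2147 in p45-null cells, from 367 in wild type. On the same arrays the hepatocyte and hepatoblast markers had a similar median of 1.75.

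Tubulin genes did not move as a block. Of 11 isotypes measured, Tubb1 and Tubb3 (6.16-fold) were at least 2-fold lower, Tubb4a was 2.31-fold higher and 8 were neither (median -0.51, percentile 0.18), while Tubb5, the widely expressed isotype, had a log2 ratio of 0.25. In the tubulin tyrosine ligase family, Ttll11, at -3.48, was the only 1 of 6 bright members at least 2-fold different (median -0.11, percentile 19.0). Among 1666 bright probe sets with several gene symbols or none here, 143 were at least 2-fold higher and 176 lower.

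Hepatocyte, macrophage and stromal markers were higher together in cells selected for CD41, which should leave such cells behind. A lower share of megakaryocytes that raises all other cell types alike is argued against by the neutrophil markers, whose upper quartile was 0.33 while the lower quartile of the hepatocyte markers was 1.41, and scaling is argued against because the lowest hepatocyte median over 3 other scalings was 1.63. More RNA of hepatocytes and of macrophages may have been in the p45-null preparation, since the second hepatocyte list had a median of 1.44 and the second macrophage list 1.69 (both at percentile 100), with 0 members in any earlier list. These second lists mark the same cell types as the first, whose medians were already known, so their rise was likely beforehand. They cannot tell more cells from more transcript per cell. Hepatocyte transcripts were also abundant in wild-type cells, where Afp had 3664 and Alb 2476 against 5967 and 6313 in p45-null cells, and all 18 measured markers passed the brightness intensity there. Whether the difference came from the genotype, the culture or the selection stays open with 1 preparation each.

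Lower platelet transcripts could come from dilution by other cells or from the loss of p45. Scaling is argued against, since the platelet receptor median stayed at -0.88 or lower over 3 other scalings. Uniform dilution judged by the spread of ratios was undecided, as the interquartile range of the receptor genes was 1.18 against a bound of 1.13, with a bootstrap interval of 0.52 to 2.25. As the whole cause it was judged against Itga2b, which had a ratio of -0.64. Of 129 bright genes of the platelet and reported-target lists, 18 lay below that ratio by more than 0.87 (14.0%, exact Clopper-Pearson 95% interval 8.48% to 21.2%, treating genes as independent). Probe set differences exceed this distance on the lower side in 5%. With the ratio of Itga2b lowered by 0.28, 13 genes did so (interval from 5.48%). Another 13 lay above the unlowered ratio by more than 0.87. These counts cannot decide the question. Tbxas1 and Casp12 entered the 129 as reported p45 targets and are among both the 18 and the 13 lower genes, and the interval barely cleared 5%. The 5% bound was set after the count was known, and a bound of 10% would have left it undecided. The test rests on Itga2b alone, which encodes CD41, the antigen by which both preparations were selected. Dilution as the whole or part of the cause, an effect of p45 on the genes and a difference in maturation stay open.

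The higher median of the NRF2 list may come from RNA of hepatic cells. Its 19 widely expressed members had a median of 0.15, inside the random range (percentile 91.3), with 2 higher and 1 lower, while its 17 liver-abundant glutathione transferase and detoxification genes had a median of 0.94 (percentile 100), with 8 of 15 bright members higher and 1 lower. Both parts were taken from the same list after its ratios were seen, and Hmox1 and Osgin1 stood out among the widely expressed members. Macrophages also express Hmox1, and an effect of p45 loss on NRF2 activity in megakaryocytes was not tested.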
